A study of Mus musculus with 4 samples.

How the data were processed

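Messenger RNA from CT26 cells was measured in 4 libraries, 2 from cells given DMSO (control) and 2 from cells given 25 µM riluzole for 24 h. RNA was extracted with Trizol, bound to poly-T beads, fragmented and copied from random hexamers, per the labels' protocols. Groups and replicate numbers were taken from the labels alone. The submitters' processing notes name HISAT2, featureCounts 1.5.0-p3, DESeq2 and edgeR, and genome build mm39; the annotation release, strandedness and the settings of these tools are not given in the sources used here.

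The authors deposited 2 tables, 1 of genes higher and 1 of genes lower with riluzole, which hold only genes with a p-value under 0.05. Raw read counts per gene were deposited for each library, per the file headers. The normalised values are a signal that the authors made from the counts: in the deposited tables each is the count divided by 1 size factor per library, 0.911 and 1.19 for the controls and 1.03 and 0.904 for riluzole. The deposited FPKM values divide each count by gene length and by 1 library total, per the file headers and the values. The log2 fold change, p-value and adjusted p were computed by the authors, per the file headers; which of the tools named made them is not given in the sources used here. The relation of deposited p-value to adjusted p implies 12601 tested genes, within 0.5 for 3648 of the 4218 genes with an adjusted p below 1. The other 77 genes have an adjusted p of 1 and group means of at most 25.3.

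The tables were joined into 4295 genes, 4095 of them protein-coding and 111 long non-coding RNAs. Listed genes held 62.63%, 63.17%, 57.19% and 57.69% of the library totals implied by FPKM, which were 15803444, 20562946, 18174251 and 15932205 counts for control replicates 1 and 2 and riluzole replicates 1 and 2. The 10 most abundant listed genes took 6.04% to 6.98% of the listed counts, and 4 to 30 listed genes per library had no count. Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, riluzole against control without covariates, with the authors' size factors as effective library sizes and no filter. Benjamini-Hochberg adjustment used the 12601 tested genes, and a gene was called at an adjusted p under 0.05. The fitted log2 fold changes had the sign of those in the authors' deposited table for all 4295 genes, with a median absolute difference of 0.00094. The median trended dispersion was 0.000932, against 0.00309 implied by the p-values of the authors' deposited table (3998 genes with a mean normalised count of at least 100); the cause of this gap was not tested. The edgeR adjusted p was smaller than that of the authors' deposited table for 3676 genes and larger for 619.

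The members of 29 gene lists were fixed before the data were examined. Lists with at least 5 called members, 24 of them, were tested for direction: higher against lower calls among members was compared with that among the other called genes by Fisher's exact test in both directions (SciPy 1.17.1), adjusted by Benjamini-Hochberg over the 24 lists. That test compares directions only, since a selection of genes gives no background for enrichment, and it treats genes as independent, which they are not. The genes named in the text follow a rule fixed with the lists: the 8 largest rises and the 8 largest falls among called protein-coding genes with a mean normalised count of at least 100 and both riluzole libraries on the same side of both controls, the 3 called members of each list with the smallest adjusted p, every listed cGAS-STING gene, and up to 3 called members that ran against their list. Cd274, Slc1a4, Slc1a2, Slc38a1, Grik5, Fen1, Pms2, Nthl1, Ogg1, Ddb1, Tpi1, Pgk1, Pfkfb4, Gpi1, Rpl8, Rpl37, Rplp0, Rpl10, Acss2, Acacb, Fads1, Hspa1b, Ahsa1, Fkbp4, Sox9, Krt8 and mt-Atp6 lie outside that rule and were named after their values were seen, as were the genes named as not listed. A few genes that the rule names are not reported here.

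Coordinates come from the deposited tables. The reference sequences held were for GRCm38 with GENCODE M21, and were used only to find, by gene identifier, near-identical copies (BLAST+ 2.17.0, at least 95% identity over at least 200 bases or 50% of the coding sequence), exons overlapping another gene by at least 50 bases (bedtools 2.31.1), GC content and transcript length. Of the 4295 genes, 4270 were matched, 563 had a copy, 1398 an overlap and 1793 either. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

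The edgeR test was tested on simulated counts with 50 genes at each of 4 fold changes among 4295: 88% of genes at 1.25-fold, 94% at 1.5-fold, 98% at 2-fold and 94% at 0.5-fold were called, with 4 unchanged genes called. All genes there shared a single dispersion, the median fitted on the listed genes. Adjustment there was over 4295 genes and not 12601, so these shares may be higher than the test used on the data would give. In a simulation of the selection, with 12601 genes of which 200 were changed, 190 changed and 623 unchanged genes reached a p-value under 0.05; refitting on those called 107 changed and 2 unchanged genes, against 138 and 15 in the fit on all genes. The median dispersion there was 0.00359 as simulated and 0.0064 as estimated after the selection. In the data, 3132 genes had an authors' adjusted p under 0.05, and the dispersion fitted on the listed genes lay below that implied by the authors. The simulation therefore cannot show how the selection acts on these data. In 100 shufflings of directions among genes, 4 of 2400 list tests passed. Shuffling breaks any tie between list members, so it cannot show how often the test passes when genes change together. Alternatives were DESeq2 1.42.0, TMM factors and DESeq2 size factors over the listed genes, library totals implied by FPKM, a filter of at least 10 counts in 2 libraries, limma 3.58.1 on log2 of FPKM plus 1 or 0.1, adjustment over the listed genes alone, the replicate number as a block, each library left out, and, for lists, every gene the authors listed. TMM and DESeq2 size factors computed over the listed genes centre on genes chosen for differing. The library totals implied by FPKM also count reads outside the listed genes. Reads and genes outside the deposited tables were not analysed here.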

Results

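CT26, a transplantable colon carcinoma cell line from BALB/c mice, was treated in culture for 24 h with 25 µM riluzole or with its solvent, DMSO. Riluzole is a drug for amyotrophic lateral sclerosis that dampens glutamatergic transmission. Messenger RNA was sequenced in 4 libraries, 2 control and 2 riluzole, to ask which transcripts respond to the drug; the study's title ties that question to cGAS-STING signalling, the pathway that senses DNA in the cytosol, and to PD-1 blockade. The values analysed cover 4295 genes, the 1780 higher and 2515 lower genes that the authors' deposited table lists at p below 0.05, of 12601 genes that its p-values imply were tested. A gene outside that table was therefore not shown to be unchanged. Listed genes held 9898486 and 12989475 counts in control replicates 1 and 2 and 10393602 and 9191717 in riluzole replicates 1 and 2, which was 57.19% to 63.17% of the library totals that the deposited FPKM values imply. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The replicates of each group differed beyond sampling noise, with a chi-square per gene of 3.60 between the controls and 3.32 between the riluzole libraries.

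Among the listed genes, riluzole mostly raised interferon-stimulated, antigen-presentation, p53-target and antioxidant genes, and mostly lowered genes of DNA replication, mitosis, DNA break repair, ribosome biogenesis and the ATF4 stress response. Of the 8 largest rises among protein-coding genes with a mean normalised count of at least 100, 7 belonged to antiviral or interferon-inducible families: Gbp3, Gbp2 and Gbp2b, which encode guanylate-binding proteins, Mx2, Ifit1, Ifit3 and Cmpk2. Gbp3 (chromosome 3, 142265787 to 142278970, mm39) went from 120 ± 7.59 normalised counts in the controls to 656 ± 63.2 with riluzole (SD, n = 2), a 5.49-fold rise, and Phf11d, the other member of the 8, rose 4.33-fold. The 8 largest falls were more varied. They comprised the glycolytic gene Gapdh (log2 fold change -2.10), Otog (-1.47), the actin-binding Avil (-1.36), Tulp1 (-1.29), the iron-scavenging lipocalin Lcn2 (-1.28), the replication-licensing factor Cdc6 (-1.22), the matrix protein Tnc (-1.17) and the checkpoint ATPase Trip13 (-1.16). Otog (chromosome 7, 45890411 to 45960858) fell from 525 ± 3.48 to 189 ± 30.5 normalised counts, and Lcn2 (chromosome 2, 32274645 to 32278264) from 780 ± 57.4 to 321 ± 18.8. Reads of Mx2, Ifit3, Phf11d, Gapdh and Cdc6 could be divided with near-identical copies (Mx1 for Mx2, Ifit3b for Ifit3 and Phf11a for Phf11d), and Avil and Tnc overlap other genes' exons, so their levels are less certain.

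In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12601 genes, 1772 genes were higher and 2501 lower at an adjusted p of 0.05, and 22 listed genes were not called. Most changes were small. The median log2 fold change was 0.45 among the genes called higher and -0.30 among those called lower, and 284 genes rose and 49 fell by at least 2-fold. Both riluzole libraries lay above both controls for 1769 of the higher genes and below them for 2500 of the lower ones, where chance alone separates 33.3% of genes. These counts start from genes already chosen for low p, so neither the high share called nor the separation of the libraries is independent evidence. The edgeR adjusted p was smaller than that of the authors' deposited table for 3676 genes and larger for 619. The authors' deposited table carries an adjusted p under 0.05 for fewer genes, 1214 higher and 1918 lower. The balance of directions also moved with the scaling. With the authors' size factors 41.5% of calls were higher, and 40.9% (1741 higher, 2513 lower) with library totals implied by FPKM. It was 51.8% (1779 higher, 1656 lower) with TMM factors and 63.1% (1779 higher, 1042 lower) with DESeq2 size factors, both over the listed genes. These 2 scalings moved every log2 fold change up by 0.10 and 0.17. Both centre on genes chosen for differing, more of them lower than higher, so an upward shift was built in.

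**Figure D1:**
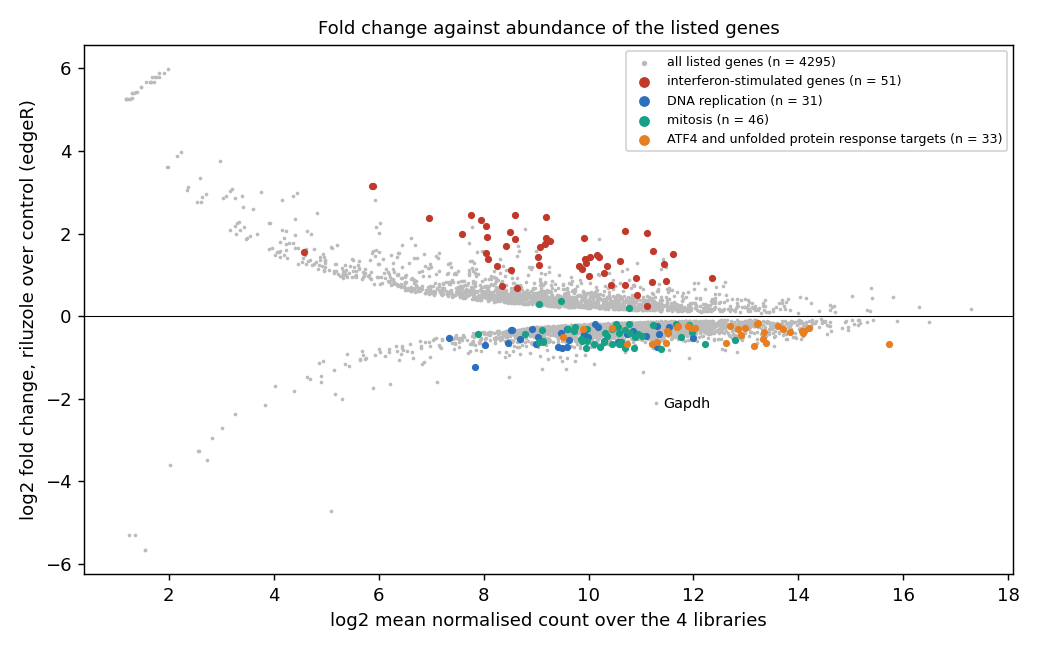
Log2 fold change of riluzole over control (vertical axis, edgeR) against the log2 mean normalised count over the 4 libraries (horizontal axis), 1 point per listed gene (n = 4295). Coloured points are the listed members of 4 gene lists: the 51 interferon-stimulated genes all lie above 0, while the 31 DNA replication genes and the 33 ATF4 and unfolded protein response targets all lie below it, as do 43 of the 46 mitosis genes.

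Interferon-stimulated genes, the antiviral effectors, sensors and signalling factors that type I interferon switches on, rose as a block. Of 53 such genes, 51 were listed and all 51 rose, with a median log2 fold change of 1.44 ± 0.63 (SD over genes), a 2.71-fold median rise. Oas3, which makes the 2′-5′-oligoadenylate that activates RNase L, rose 4.15-fold from 642 ± 54.2 to 2653 ± 231 normalised counts (SD, n = 2). Oasl2 rose 4.04-fold (882 ± 95 to 3543 ± 274) and Oasl1 2.85-fold (1616 ± 146 to 4596 ± 308); their edgeR Benjamini-Hochberg adjusted p values were 2.15e-20 and 5.84e-19. Ifit1 (chromosome 19, 34618271 to 34627409), whose product binds viral RNA that lacks host cap methylation, rose from 186 ± 24.6 to 977 ± 159. The smallest rise in the list was 0.24 and the largest 3.15 on the log2 scale. Ifnb1, the interferon beta gene, and Ifi44l were the 2 members not listed. Against the other called genes, the split of 51 higher to 0 lower gave an adjusted p of 5e-19 in Fisher's exact test (both directions, Benjamini-Hochberg over 24 lists). The count was also 51 when adjusted over the list alone, and 50 of the 51 had an adjusted p under 0.05 in the authors' deposited table. Listed members had already been chosen for low p, so adjustment over a list alone, here and below, is not independent support. The direction held for all 51 genes under each of the 4 scalings; 24 members have a near-identical copy or an overlapping gene.

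Genes of the cGAS-STING pathway went both ways. Of 23 members, 10 were listed, 7 higher and 3 lower. Irf7 (chromosome 7, 140842619 to 140846394), a transcription factor that drives type I interferon genes, rose 3.68-fold from 499 ± 6.52 to 1837 ± 121 normalised counts (SD, n = 2; log2 fold change 1.88 ± 0.06, SE). Smaller rises were seen for Tmem203 (log2 fold change 0.61), Samhd1 (0.54), a dNTP hydrolase that limits DNA accumulation, the DNA-binding Ifi203 (0.52) and Ifi204 (0.36), Sting1 (0.30) and the ubiquitin ligase Trim56 (0.24). Sting1 (chromosome 18, 35866732 to 35873607), the adaptor of the pathway, went from 600 ± 11.7 to 738 ± 15.4, with an adjusted p of 0.00183 in edgeR (Benjamini-Hochberg) and of 0.0492 in the authors' deposited table. Banf1, which shields DNA from cGAS, fell by 0.42 on the log2 scale. Cgas (chromosome 9, 78337808 to 78350519), the DNA sensor, went from 386 ± 27.4 to 301 ± 39.3 and the kinase gene Tbk1 from 1160 ± 74.9 to 1010 ± 56.3. Both passed in edgeR, with Benjamini-Hochberg adjusted p values of 0.00645 and 0.0131, and neither did in the authors' deposited table (0.117 and 0.148).

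The falls of Cgas and Tbk1 were the least secure of the pathway. In edgeR with Benjamini-Hochberg adjustment, Cgas was no longer called without control replicate 2 (adjusted p = 0.103) or riluzole replicate 1 (0.263), and Tbk1 was not called without control replicate 1 (0.263) or riluzole replicate 1 (0.255). DESeq2 ended both calls at nearly the same log2 fold changes (-0.36 for Cgas and -0.20 for Tbk1), whereas TMM and DESeq2 size factors over the listed genes ended them with smaller falls, -0.27 and -0.20 for Cgas and -0.10 and -0.03 for Tbk1. As a list, the 7 to 3 balance of the cGAS-STING pathway was not shown to differ from that of the other called genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.156). It passed in 3 alternatives, with p = 0.0177 in the same exact test on DESeq2 calls, 0.0126 on the adjusted p of the authors' deposited table and 0.0217 without riluzole replicate 1, in a range of 0.0126 to 0.39 over 16 alternatives. The counts were the same 7 and 3 when adjusted over the list alone. Irf3, Ikbke and Trex1 were among the 13 members not listed. Ifi203 and Ifi204 have near-identical copies, and Banf1, Cgas and Tmem203 overlap a neighbouring gene.

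**Figure D2:**
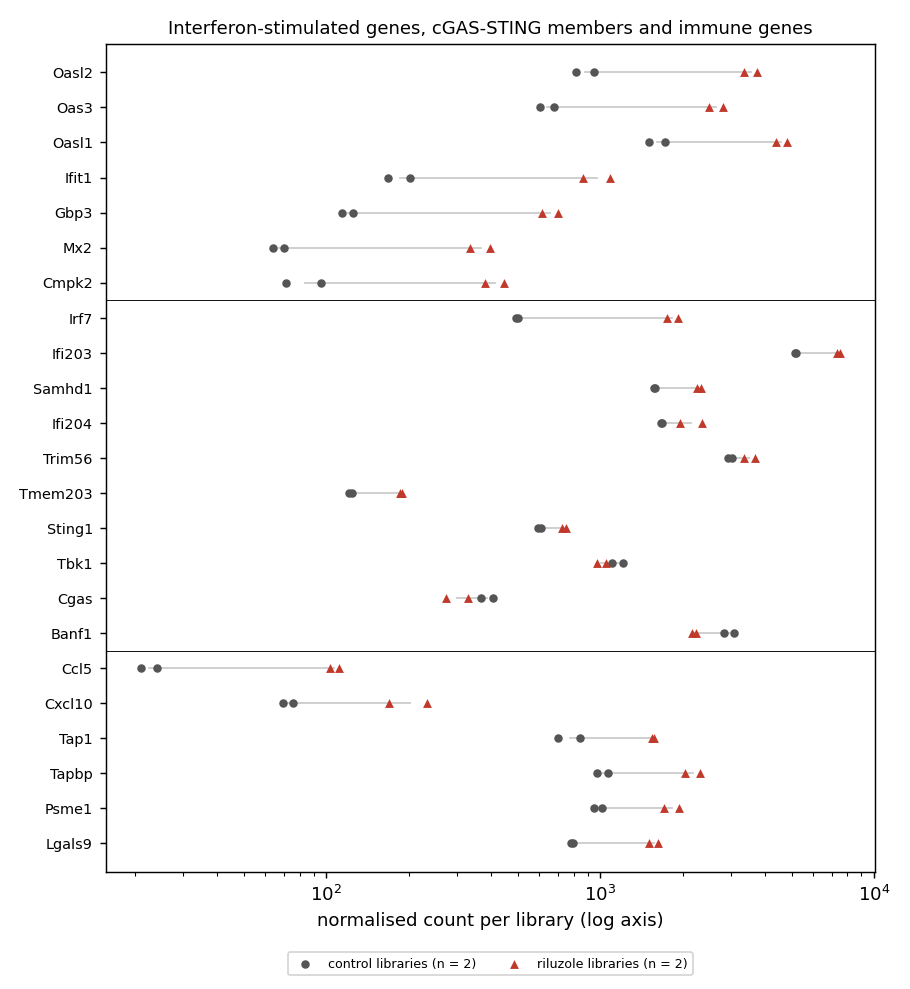
Normalised count per library (horizontal log axis) for interferon-stimulated genes (top), listed cGAS-STING members (middle) and chemokine, antigen-presentation and checkpoint genes (bottom); circles are the 2 control and triangles the 2 riluzole libraries, and grey lines join the group means. Irf7 went from 499 to 1837 while Cgas went from 386 to 301.

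Most listed genes through which tumour cells are seen by T cells rose. Of 22 genes of antigen presentation by MHC class I, 15 were listed, and 13 rose and 2 fell. The peptide transporter gene Tap1 rose 2.03-fold (774 ± 101 to 1561 ± 26.3 normalised counts; SD, n = 2), Tapbp, which encodes the chaperone that tethers MHC class I to it, 2.14-fold (1021 ± 65.8 to 2183 ± 202), and the proteasome activator gene Psme1 1.84-fold (986 ± 48.5 to 1825 ± 163). Calr and Canx, which encode the chaperones calreticulin and calnexin, fell by 0.37 and 0.23 on the log2 scale; the fall of Canx was not called with DESeq2 size factors over the listed genes (log2 fold change -0.06). The 13 to 2 split passed Fisher's exact test with a Benjamini-Hochberg adjusted p of 0.00173. Among the 6 members with neither copies nor overlapping exons the split was 4 to 2 and the exact test gave an adjusted p of 0.518, in a range of 0.000919 to 0.518 over 16 alternatives. Tap1 and Tapbp overlap other genes' exons, and CT26 carries BALB/c alleles, which differ at the H2 genes from the reference mouse strain.

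Chemokines and cytokines went both ways. Of 30 genes, 10 were listed, 7 higher and 3 lower. Ccl5, which attracts T cells, rose 4.77-fold from 22.6 ± 2.21 to 107 ± 5.99 normalised counts (SD, n = 2), and Cxcl10, an interferon-induced T cell attractant, 2.76-fold from 72.8 ± 4.19 to 202 ± 45.3. Csf1, the macrophage growth factor, fell from 18836 ± 2378 to 12947 ± 47.7, and Vegfa, the angiogenic factor, fell by 0.30 on the log2 scale. Mif fell by 0.14, a change that vanished with DESeq2 size factors over the listed genes (log2 fold change 0.02) and was not called in edgeR without control replicate 2 or riluzole replicate 1 (Benjamini-Hochberg adjusted p = 0.0784 and 0.163). Of 17 immune checkpoint ligands, 5 were listed. Lgals9 rose 1.98-fold, Cd274, the PD-L1 gene, 1.51-fold (164 ± 17.3 to 247 ± 1.32) and Cd80 1.30-fold, whereas Nectin2 and Pvr, ligands of the TIGIT and CD226 receptors, fell by 0.57 and 0.21 on the log2 scale; Pvr was not called with DESeq2 size factors over the listed genes (log2 fold change -0.05). Neither list was shown to differ from the other called genes in Fisher's exact test (Benjamini-Hochberg adjusted p = 0.156 and 0.749), with 10 and 5 members to test. Mif has near-identical copies, and Cxcl10, Cd274 and Nectin2 overlap other genes, which makes their levels less certain. The chemokine, antigen-presentation and checkpoint lists kept their counts when adjusted over the list alone.

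Nearly all listed genes of DNA replication and mitosis fell. Of 47 DNA replication genes, 31 were listed and all 31 fell, with a median log2 fold change of -0.50 ± 0.21 (SD over genes). Cdc6 (chromosome 11, 98798627 to 98814766) fell to 0.428 of its control level, from 320 ± 28.9 to 136 ± 10.6 normalised counts (SD, n = 2), and the origin recognition gene Orc2 to 0.600 (3179 ± 3.10 to 1908 ± 51.0). Mcm5, part of the replicative helicase, fell from 1833 ± 26.6 to 1184 ± 16.4, and Rrm1, a subunit of ribonucleotide reductase, from 4814 ± 58.5 to 3311 ± 36.8. Of 55 mitosis genes, 46 were listed, of which 43 fell and 3 rose (median log2 fold change -0.46 ± 0.26). Top2a, which untangles chromosomes, fell from 5837 ± 129 to 3685 ± 144, the spindle midzone gene Prc1 from 2085 ± 27.4 to 1217 ± 4.15, and the cytokinesis gene Anln from 8570 ± 13.2 to 5695 ± 167. Ccnb2 (log2 fold change 0.36), Pttg1 (0.30) and Kif20a (0.20) ran the other way. Pttg1 and Kif20a did not pass in the authors' deposited table (adjusted p = 0.0863 and 0.0524), and Kif20a was not called in edgeR without control replicate 2 (Benjamini-Hochberg adjusted p = 0.0753). Fisher's exact test gave Benjamini-Hochberg adjusted p values of 5.93e-07 for replication and 1.02e-06 for mitosis. Adjusted over the list alone the counts were the same, and the authors' deposited table gave 0 higher and 26 lower, and 1 higher and 40 lower, at an adjusted p under 0.05. The medians stayed negative under the 4 scalings, the smallest falls being -0.34 and -0.29. Levels of Orc2, Top2a, Prc1 and Kif20a, which overlap other genes, and of Cdc6, which has a near-identical copy, are less certain.

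Listed genes of DNA break repair mostly fell. Of 53 genes of double-strand break repair and damage signalling, 21 were listed, and 20 fell and 1 rose (median log2 fold change -0.45 ± 0.25, SD over genes). Xrcc6, the Ku70 gene of end joining, fell from 2358 ± 35.5 to 1743 ± 96.8 normalised counts (SD, n = 2), and the homologous recombination genes Rad51ap1 and Blm from 481 ± 19.1 to 271 ± 29.9 and from 478 ± 5.27 to 291 ± 8.35. Atm, the kinase that signals breaks, was the member that rose (log2 fold change 0.28); it did not pass in the authors' deposited table (adjusted p = 0.0774) nor in edgeR without riluzole replicate 1 (Benjamini-Hochberg adjusted p = 0.145). The list passed Fisher's exact test with a Benjamini-Hochberg adjusted p of 0.000717; its median shrank to -0.28 with DESeq2 size factors over the listed genes. Genes of mismatch, base excision and nucleotide excision repair went in both directions, 5 higher and 5 lower among the 10 listed of 35 (exact test, adjusted p = 0.783). The split was 2 higher and 3 lower by the adjusted p of the authors' deposited table, and 5 and 2 with DESeq2 size factors over the listed genes. Ercc1 and Tdg fell by 0.86 and 0.88 on the log2 scale, as did Fen1 (log2 fold change -0.86), Pms2 (-0.33) and Lig1 (-0.26), while Nthl1 (0.52), Ercc5 (0.47), Ogg1 (0.32) and Ddb1 (0.18) were among those that rose. Of these, Fen1, Pms2, Nthl1 and Ogg1 did not pass in the authors' deposited table (adjusted p = 0.145, 0.0947, 0.0677 and 0.055). The log2 fold change of Lig1 shrank to -0.17 without control replicate 1. With TMM and DESeq2 size factors over the listed genes it was -0.17 and -0.10, and Lig1 was not called. Xrcc6, Ercc1, Tdg, Fen1, Pms2, Lig1, Ogg1 and Ddb1 overlap other genes, and Tdg has 4 near-identical copies, so their levels are less certain. Adjusted over the list alone, the repair lists kept their counts of 1 higher and 20 lower, and of 5 and 5.

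Targets of p53 mostly rose. Of 28 such genes, 17 were listed, 14 higher and 3 lower, with a median log2 fold change of 0.37 ± 0.38 (SD over genes). Mdm2, the ubiquitin ligase that p53 induces against itself, rose 1.78-fold from 4453 ± 201 to 7955 ± 12.7 normalised counts (SD, n = 2), and Ccng1 1.57-fold from 3709 ± 94.5 to 5824 ± 32.2. Gadd45a, a growth arrest gene also induced by ATF4, fell from 5165 ± 25.1 to 3376 ± 25.4. Plk3 and Plk2 fell by 0.21 and 0.11 on the log2 scale with the authors' size factors; with DESeq2 size factors over the listed genes neither was called and Plk2 changed sign (log2 fold change 0.05). Plk2 was also not called in edgeR without control replicate 2, riluzole replicate 1 or riluzole replicate 2 (Benjamini-Hochberg adjusted p = 0.412, 0.0972 and 0.111). The list passed Fisher's exact test (Benjamini-Hochberg adjusted p = 0.00173), with the same counts adjusted over the list alone; Gadd45a and Plk3 overlap other genes and are less certain.

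**Figure D3:**
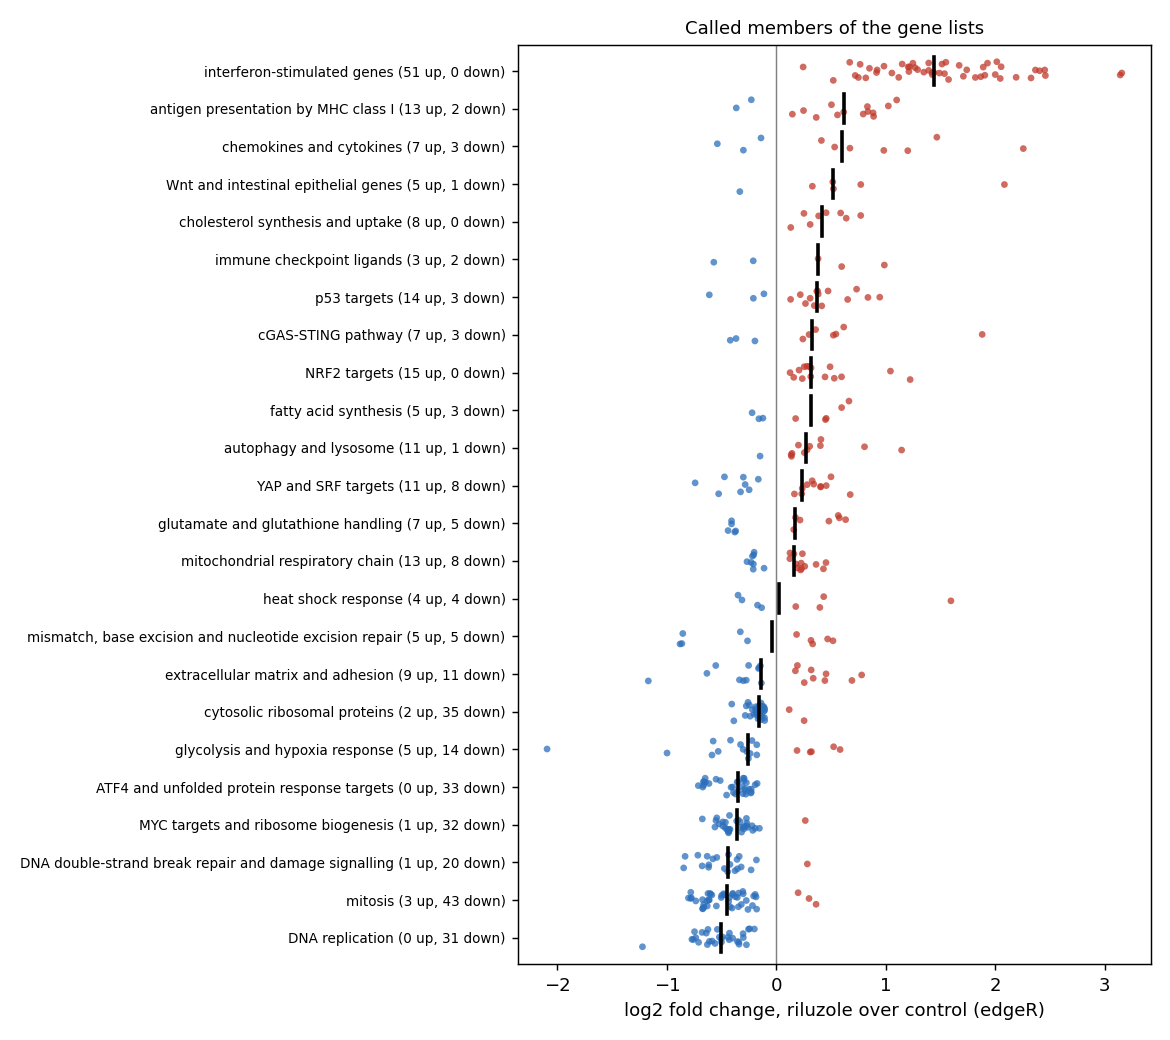
Log2 fold change of riluzole over control (horizontal axis, edgeR) for the called members of the 24 lists with at least 5 of them, 1 point per gene, red above and blue below 0; black bars are medians, and the labels give the number of members up and down. Medians run from 1.44 for interferon-stimulated genes to -0.50 for DNA replication. With DESeq2 size factors over the listed genes the medians of the listed ribosomal protein, extracellular matrix and excision repair genes turn positive. The excision repair median is also positive with TMM factors over the listed genes (0.06). That of heat shock genes turns negative with the library totals implied by FPKM.

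Every listed target of ATF4 and the unfolded protein response fell. These were 33 genes of 47, with a median log2 fold change of -0.35 ± 0.17 (SD over genes), and all 33 also passed an adjusted p of 0.05 in the authors' deposited table. Aldh1l2, a mitochondrial folate enzyme induced by ATF4, fell from 11246 ± 142 to 6860 ± 273 normalised counts (SD, n = 2), the endoplasmic reticulum chaperone gene Hyou1 from 7724 ± 132 to 4918 ± 11.97, and Ppp1r15a, which encodes the GADD34 subunit that reverses eIF2α phosphorylation, from 13016 ± 110 to 8234 ± 268. The list gave an adjusted p of 2.74e-07 in Fisher's exact test (Benjamini-Hochberg), and the direction of all 33 genes held under the 4 scalings, though with DESeq2 size factors over the listed genes the median shrank to -0.19 and 24 genes were called. Aldh1l2 overlaps another gene. Slc7a11, Atf3 and Sesn2, well-known members of this response, were not listed.

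Listed genes for making ribosomes also fell. Of 40 MYC targets and ribosome biogenesis genes, 33 were listed, 32 lower and 1 higher (median log2 fold change -0.36 ± 0.17, SD over genes; Fisher's exact test, Benjamini-Hochberg adjusted p = 3.88e-06). The nucleolar genes Nop58, Npm1 and Nop56 fell from 6396 ± 36.2 to 4333 ± 59.9, from 20284 ± 450 to 13833 ± 425 and from 9936 ± 47.1 to 7072 ± 8.58 normalised counts (SD, n = 2). With DESeq2 size factors over the listed genes the median of this list shrank to -0.20 and 22 genes were called lower. Odc1, an enzyme of polyamine synthesis and a MYC target, rose 1.20-fold. Cytosolic ribosomal protein genes shifted down by less, and that shift depended on the scaling. Of 59, 42 were listed; with the authors' size factors 35 fell, 2 rose (Rps2 and Rpl6) and 5, among them Rpl8, Rpl37, Rplp0 and Rpl10, were not called. The called members had a median of -0.16 ± 0.11 and an adjusted p of 6.11e-06 in the exact test. Over all 42 the median was -0.14 with the authors' size factors and -0.17 with library totals implied by FPKM. It turned positive (0.02) with DESeq2 size factors over the listed genes. Adjusted over the list alone, 36 fell and 2 rose, and for the other 2 lists these counts were the same as over all genes. Rps27, Rpl30 and Rps13 had the smallest adjusted p and fell by 0.41, 0.39 and 0.29 on the log2 scale. Leaving out control replicate 2 or riluzole replicate 1 cut the 35 lower calls to 17 and 14 (exact test, adjusted p = 0.00303 and 0.0375). With DESeq2 size factors over the listed genes 26 of the 42 lay above 0 and 16 below, and the list no longer passed the exact test (adjusted p = 0.494, and 0.101 with TMM factors, in a range of 4.28e-07 to 0.494 over 15 alternatives). Of the listed ribosomal protein genes 34 have near-identical copies, as do Npm1, Nop56 and Odc1, and Nop58 overlaps another gene, so these levels are uncertain. Rpl6 was not called in edgeR without control replicate 1, control replicate 2 or riluzole replicate 2 (Benjamini-Hochberg adjusted p = 0.302, 0.0897 and 0.520).

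**Figure D4:**
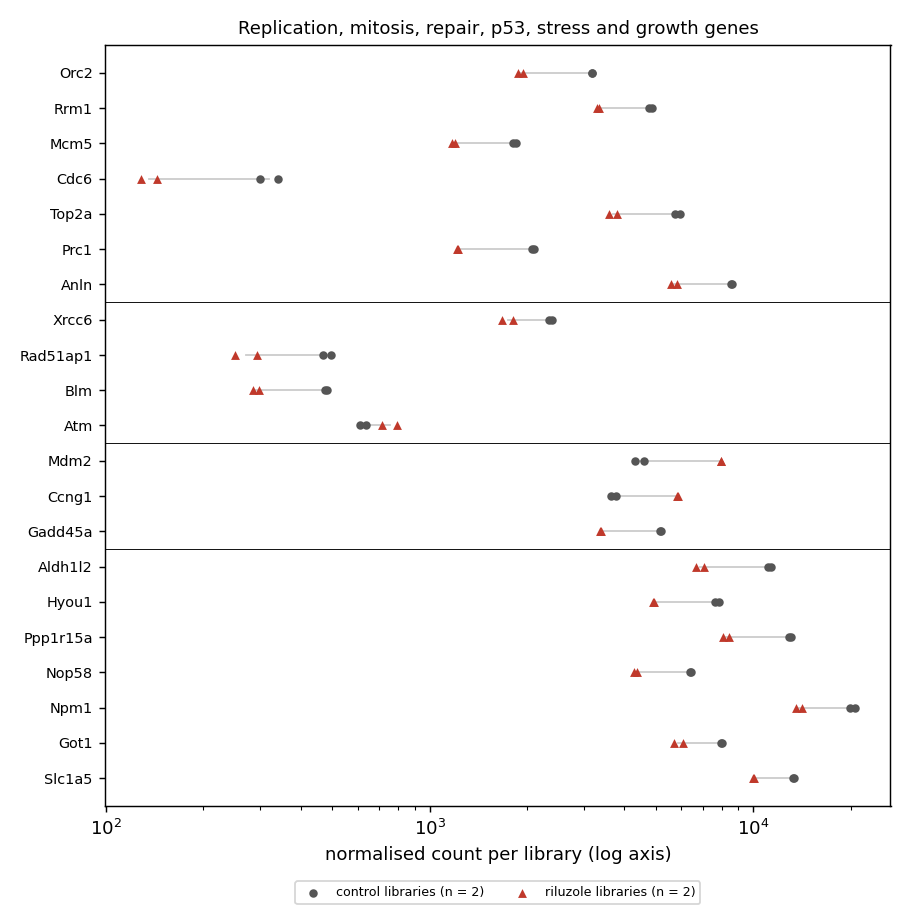
Normalised count per library (horizontal log axis) for genes of replication and mitosis, double-strand break repair, p53 targets, and stress, ribosome biogenesis and glutamate handling, from top to bottom; circles are the 2 control and triangles the 2 riluzole libraries, and grey lines join the group means. Mdm2 went from 4453 to 7955 and Ccng1 from 3709 to 5824, while Orc2 went from 3179 to 1908.

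Glutamate handling, the process for which riluzole is best known, changed in parts. Of 42 glutamate and glutathione genes, 12 were listed, 7 higher and 5 lower. The balance turned in some alternatives, to 3 higher and 5 lower with DESeq2, 2 and 5 by the adjusted p of the authors' deposited table and 4 and 5 without control replicate 2. The neutral amino acid transporter gene Slc1a5, which brings in glutamine, fell from 13295 ± 90.6 to 10005 ± 59.5 normalised counts (SD, n = 2), and the transaminase gene Got1 from 7966 ± 31.3 to 5866 ± 261. Slc1a4 and Slc1a2 also fell, by 0.41 and 0.38 on the log2 scale, while Slc38a1, another glutamine transporter gene, rose by 0.56 but did not pass in the authors' deposited table (adjusted p = 0.121). Of the 23 ionotropic and metabotropic glutamate receptor genes in the list, 1 was listed, Grik5, with a log2 fold change of 0.48. The 7 to 5 balance was not shown to differ from that of the other called genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.321). Of 22 ion channel genes that riluzole is known to bind or modulate, 3 were listed, all higher. The potassium channel gene Kcnn4 rose 1.34-fold (1282 ± 9.69 to 1714 ± 14.8). Cacna1a went from 1034 ± 57.4 to 1204 ± 91.2. It passed in edgeR (Benjamini-Hochberg adjusted p = 0.00460) but not in the authors' deposited table (0.0924). In edgeR, Cacna1a was not called without control replicate 2 or riluzole replicate 1 (Benjamini-Hochberg adjusted p = 0.109 and 0.213). Slc1a2 and Cacna1a overlap other genes.

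Every listed target of NRF2, the antioxidant regulator, rose. Of 22 NRF2 targets, 15 were listed (median log2 fold change 0.31 ± 0.32, SD over genes), with an adjusted p of 6.11e-06 in Fisher's exact test (Benjamini-Hochberg). Gstm1, a glutathione transferase gene, rose 2.06-fold from 359 ± 18.4 to 741 ± 25.9 normalised counts (SD, n = 2), the pentose phosphate enzyme gene Pgd 1.51-fold from 2340 ± 78.9 to 3529 ± 5.54, and the ferritin gene Fth1 from 27766 ± 2041 to 39000 ± 1425. Hmox1, Nqo1, Gclc and Slc7a11 were not listed. Of 14 aryl hydrocarbon receptor targets, 2 were listed. The receptor gene Ahr rose 1.51-fold (684 ± 3.35 to 1034 ± 82.4), and Nfe2l2, which encodes NRF2, went from 2451 ± 183 to 2734 ± 16.8. Nfe2l2 passed in edgeR (Benjamini-Hochberg adjusted p = 0.0125) and not in the authors' deposited table (0.102), and was not called without control replicate 1, riluzole replicate 1 or riluzole replicate 2 (0.417, 0.0591 and 0.0794). Cyp1a1, Cyp1b1 and Tiparp were not listed, and Gstm1 has a near-identical copy and Ahr an overlapping gene. Adjusted over the list alone, the counts for glutamate, ion channel, NRF2 and aryl hydrocarbon receptor genes were the same.

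Glycolysis and hypoxia genes went both ways. Of 34, 20 were listed, 14 lower, 5 higher and 1, Gpi1, not called (log2 fold change 0.10); adjusted over the list alone it was 14 and 6. Hk2, which commits glucose to glycolysis, fell from 3635 ± 244 to 2510 ± 27.6 normalised counts (SD, n = 2), and the mitophagy receptor gene Bnip3 from 933 ± 5.60 to 468 ± 63.8. Aldoa (log2 fold change 0.31), Hk1 (0.32), Pfkm (0.52), Tpi1 (0.19) and Pfkfb4 (0.58) rose. Fisher's exact test gave a Benjamini-Hochberg adjusted p of 0.321, and with DESeq2 size factors over the listed genes 8 were called lower and 6 higher, with the median of the 20 at -0.08 in place of -0.25. Gapdh (chromosome 6, 125138678 to 125143430), often used as a reference gene, had the deepest fall, from 4063 ± 1062 to 933 ± 476, and the widest replicate spread of the listed genes with a mean normalised count of at least 100: its libraries held 4814 and 3312 normalised counts in the controls and 1270 and 597 with riluzole. Its adjusted p was 5.41e-12 in edgeR (Benjamini-Hochberg) and 0.00204 in the authors' deposited table. Gapdh has 90 near-identical copies in the mouse genome and its exons overlap Iffo1; Bnip3 has 4 such copies and Tpi1 and Gpi1 have 1 each, and Hk1 and Pfkm overlap other genes.

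Markers of other cell types were nearly absent from the listed genes. Of 26 immune cell markers, Cd68, a lysosomal protein gene that other cells express too, was the 1 listed, and it rose 1.62-fold from 200 ± 23.2 to 326 ± 1.44 normalised counts (SD, n = 2; edgeR, Benjamini-Hochberg adjusted p = 1.70e-05). None of 14 markers of endothelial cells and blood was listed. Of 46 replication-dependent histone genes, whose transcripts lack poly-A tails, H2bc21 was listed, with 50.7 ± 2.76 normalised counts in the controls and 105 ± 28.1 with riluzole (edgeR, Benjamini-Hochberg adjusted p = 0.000229). Adjusted over the list alone these counts were the same.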

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

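The calls from the adjusted p of the authors' deposited table, and the lists without genes with copies or overlapping exons, were chosen as alternatives after seeing the data. Over 14 alternatives the number of genes higher ran from 1214 to 1779, lower from 1042 to 2513, and at least 2-fold from 69 to 364 higher and 8 to 53 lower. The lower count was 1656 with TMM and 1042 with DESeq2 size factors over the listed genes, which left 31 genes at least 2-fold lower. At least 2-fold, 168 genes were higher and 25 lower by the authors' deposited table, and 69 and 8 with limma on log2 of FPKM plus 1. Leaving out 1 library gave 1518 to 1632 higher and 2144 to 2305 lower genes. The replicate block gave 1763 higher and 2510 lower genes and changed neither the result of a list nor the call of a named gene. The difference between replicates in the controls and that in the riluzole libraries correlated at 0.0776 across 3998 genes. Those genes were chosen for low p, and each group gives a single difference. Whether libraries of the same replicate number were paired can thus be neither shown nor excluded. Between 10 and 13 lists passed Fisher's exact test over 16 alternatives. With Benjamini-Hochberg adjusted p values, the cGAS-STING list passed at 0.0177 on DESeq2 calls and 0.0126 on the authors' deposited table, and ran from 0.0217 to 0.153 with 1 library left out; Wnt and epithelial genes ran from 0.0202 to 0.249. Antigen presentation did not pass without copies and overlaps (0.518, on 6 genes), nor cholesterol genes with DESeq2 size factors over the listed genes (0.0573), nor ribosomal proteins with those (0.494) or TMM (0.101), while the respiratory chain passed with both (0.00873 and 0.0161). Of 129 named genes, 24 were no longer called in at least 1 alternative. The sign changed for 5, all with DESeq2 size factors over the listed genes: Mif (log2 fold change 0.0247), Plk2 (0.0512), Scd1 (0.0056), Scd2 (0.0418) and Sqstm1 (0.0161). These sign changes follow from the shift of 0.17 that this scaling gives every gene; for the other changes the cause was not tested. The other lists kept their side of the threshold, but the balance of higher and lower calls turned or evened out in some alternatives for glutamate, fatty acid, excision repair, extracellular matrix, heat shock and respiratory chain genes. The gene set tests fry and camera were not run because the tables hold a selection. With 2 libraries per group, a gene with few counts is called only at a large fold change.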

Other observations

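Tests of GC content, gene length and near-identical copies were written before their values were seen; those of scaling, other cell types and the glycolysis list were chosen after the result was seen. Listed genes of cholesterol synthesis and of lysosomes mostly rose. All 8 listed of 25 cholesterol genes rose (median log2 fold change 0.42 ± 0.21, SD over genes), among them Acat2 (log2 fold change 0.64) and Idi1 (0.77); Fisher's exact test gave a Benjamini-Hochberg adjusted p of 0.00173, and 0.0573 with DESeq2 size factors over the listed genes, in a range of 0.00158 to 0.0573. DESeq2, or leaving out control replicate 1, called 5 of the 8, and 3 passed in the authors' deposited table, too few to test. Of 35 autophagy and lysosome genes, 12 were listed, 11 higher and 1 lower (adjusted p = 0.00122 in the exact test, Benjamini-Hochberg). Atg9b rose from 1660 ± 113 to 3676 ± 34.8 normalised counts (SD, n = 2), the lysosomal protease gene Ctsd from 2985 ± 72.3 to 5218 ± 112, and Ctsa by 0.40 on the log2 scale, while the autophagy receptor gene Sqstm1 fell by 0.15 and changed sign with DESeq2 size factors over the listed genes (0.02). Atg9b, Ctsd, Ctsa, Sqstm1, Acss2 and Elovl1 overlap other genes, and Acat2, Idi1, Elovl6 and Scd2 have near-identical copies, so their levels are uncertain. Of 17 fatty acid genes, 5 rose (Elovl6, Acss2, Acacb, Fads2 and Fads1) and 3 fell (Elovl1, Scd1 and Scd2; adjusted p = 0.346 in the exact test, Benjamini-Hochberg); Scd1 and Scd2 also changed sign with that scaling, and Acss2 and Acacb did not pass in the authors' deposited table (adjusted p = 0.0505 and 0.1015). In edgeR (Benjamini-Hochberg), Elovl1 was not called without riluzole replicate 1 (adjusted p = 0.0588), and Scd2 without control replicate 1, riluzole replicate 1 or riluzole replicate 2 (0.286, 0.0724 and 0.0867). When adjusted over the list alone, the counts of all lists of these paragraphs were the same.

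Structural genes went both ways. The intermediate filament gene Vim rose from 32617 ± 1373 to 52592 ± 962 normalised counts (SD, n = 2) and Itga3 by 0.44 on the log2 scale, and Thbs2 fell by 0.55; of 53 extracellular matrix and adhesion genes 9 rose and 11 fell, but 13 lay above 0 and 7 below with DESeq2 size factors over the listed genes. Among 38 YAP and SRF targets 11 rose, such as Cnn2 (log2 fold change 0.67), and 8 fell, such as Amotl2 (-0.53), Ajuba (-0.48) and F3 (-0.74). Heat shock genes split 4 to 4, with Hspa1b (1.59), Hsp90ab1 (0.43), Hspa8 (0.40) and Ahsa1 higher and Chordc1 (-0.35), Hspa4, Hspb8 and Fkbp4 lower; without control replicate 1 it was 2 higher and 3 lower. The epithelial genes Krt20 (0.77), Krt18 (0.51), Sox9 and Cd44 (0.33) rose, as did Krt8 at low counts (3.88 ± 0.73 to 16.6 ± 1.56), and Znrf3 fell by 0.33. Hspa1b, Ahsa1, Hspb8, Krt8 and Znrf3 did not pass in the authors' deposited table (adjusted p = 0.0984, 0.126, 0.0751, 1 and 0.105). Of the listed respiratory chain genes, all 7 encoded by mitochondrial DNA rose, by 0.12 to 0.43. The largest of these rises, that of mt-Atp6, did not pass in the authors' deposited table (adjusted p = 0.0919). Nuclear ones split into 6 higher, such as Ndufb3 (0.45) and Cox6c (0.26), and 8 lower, such as Ndufa9, Sdha and Cyc1. Of these falls 2 were called with TMM and 0 with DESeq2 size factors over the listed genes. None of these 5 lists passed Fisher's exact test (Benjamini-Hochberg adjusted p = 0.821, 0.233, 0.783, 0.151 and 0.137), though the epithelial list did without riluzole replicate 2 (0.0202, in a range of 0.0202 to 0.294) and the respiratory chain did with TMM (0.0161) and DESeq2 size factors over the listed genes (0.00873, in a range of 0.00873 to 0.789). The log2 fold change of Hspb8 was -0.17 with all libraries, -0.13 without control replicate 2 and -0.15 without riluzole replicate 1. That of Znrf3 was -0.28 without riluzole replicate 2. With TMM and DESeq2 size factors over the listed genes neither gene was called (-0.07 and -0.01 for Hspb8, -0.24 and -0.17 for Znrf3). Hspa1b, Hspa8, Krt8 and Ndufb3 have near-identical copies and Ahsa1, Cox6c and Ndufa9 overlap other genes.

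The median log2 fold change of the 51 interferon-stimulated genes was 1.4653 (SD 0.64 over genes) after removing a trend on GC content and transcript length that took up 2.25% of the variance of 4248 genes, which argues against composition as the source of their rise. Scaling moves all genes of a library alike, and the 3 other scalings moved them by -0.025 to 0.17 on the log2 scale, which left the lowest median at 1.4131 (SD 0.63). Against the other called genes, the 51 to 0 split also passed Fisher's exact test with TMM and with DESeq2 size factors over the listed genes (Benjamini-Hochberg adjusted p = 4.63e-14 and 5.50e-10), which argues against scaling as the source. Immune cells could also carry such genes, but the libraries came from a carcinoma cell line treated in culture, a design with no stated source of them. Of 26 immune markers 1 was higher, Cd68, which other cells express too. Nothing here points to immune cells, though markers outside the tables were not shown to be unchanged.

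The fall of Gapdh came with replicate ratios of 1.453 in the controls and 2.129 with riluzole, and a spread of 0.814 on the log2 scale against a median of 0.064 for genes without copies. A fall of glycolysis as a whole at that size was argued against by the other 12 called members without copies, whose median log2 fold change was -0.2482 (SD 0.43 over genes). Reads divided among its 90 copies might widen the spread; genes with copies spread 1.069 times as much as others at the same mean count (95% bootstrap interval 0.979 to 1.144, 531 genes), and those with 10 or more copies 1.155 times (0.934 to 1.477, 35 genes). A true fall and a loss of reads to copies cannot be told apart here. Its level was also low for the pathway, with 56.76 FPKM in the controls against 888.2 for Pgk1 and 189.8 for Tpi1 in the authors' deposited table.

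The joint fall of replication and mitosis genes, with a median log2 fold change of -0.49 over 77 called members, stayed at -0.4447 (SD 0.25 over genes) after the trend on GC content and transcript length was removed. Over 4 scalings the median came up to -0.3276 (SD 0.25), with 74 of 77 members still below 0. The direction held, but the median did not clear the bound chosen for this test by more than the SD over genes. The test therefore cannot tell whether scaling was a source of the fall. That median came with DESeq2 size factors over the listed genes, which centre on genes chosen for differing. With library totals implied by FPKM the listed members had medians of -0.53 for replication and -0.48 for mitosis. With the authors' size factors these were -0.50 and -0.46. The exact size of the fall cannot be settled without the genes outside the tables.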
